A study of Mus musculus with 46 samples.

How the data were processed

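Liver RNA of 46 male B6C3F1 mice was measured on 2-colour Agilent arrays, with 1 mouse per array and 43379 spots per array once control spots are left out. Per the labels, animals were caged singly, RNA came from 1 lobe of each liver, and the replicates of a group are separate animals. The liver RNA carried Cy5 on every array and a universal mouse reference RNA carried Cy3, so a log2 ratio of Cy5 over Cy3 is higher where the liver holds more of a transcript. No dyes were swapped. Per the file headers the arrays were read with Agilent Feature Extraction 10.1.1.1, and the files give the median intensity of each spot, its local background and a processed intensity that Agilent's software had background-subtracted and dye-normalized. The arrays lay on 12 slides scanned on 7 days. Array values over all probes correlated between 0.932 and 0.987, and no array was a copy of another.

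The log2 values in the authors' series table came with no stated scale, centring or direction, so each column was set against its own array. The authors' values followed log2(Cy5/Cy3) after loess without background correction, with a median correlation over probes of 0.997 (lowest array 0.996) and a median slope of 0.993. The correlation was 0.994 with the values used here and 0.867 with Agilent's processed signals. The direction and the log base are thereby known, each column is centred near 0 with array medians of -0.035 to -0.014, and the steps that gave the authors' values are not given in the sources used here.

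The spot signals were corrected with normexp (offset 50) on the median signal and the median local background. The plan had named the mean signal, for which the median was used because the files hold medians. Ratios were normalized by loess within each array, with control and outlier spots given no weight, and spots of 1 probe were averaged. No probe was saturated in Cy5. A probe was kept if Cy5 was well above background on at least 4 arrays of at least 1 group, which left 20634 of 41174 probes. Each gene was read from its kept probe with the highest mean Cy5 signal. A probe was named only where its RefSeq accession was in a table of assembly GRCm38.p6, which gave 23374 probes a name (16535 symbols) and left 17800 without one. The array header names another build, so no coordinates are given.

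A mean per group was fitted over all 46 arrays with limma 3.58.1 (lmFit, eBayes with an intensity trend, R 4.3.3), and p-values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. Every adjusted p of a gene comes from this limma fit, and a value such as "a ± b" gives a log2 change and its standard error. Comparisons were each dose against the control of its time, a dose trend linear in dose rank, 300 against 150 mg/kg, the difference of a dose effect between times, and the controls of the times. Where a gene was not well above background on any array of a group, only a bound is given for the dose comparisons, and a gene is called measured on an array where a probe of it was well above background. The bound sets the mean of the brighter group against the mean of the dimmer one, in which each array takes the higher of the probe's own Cy5 signal and the lowest signal well above background, on log2 Cy5 values after loess and Aquantile. Where the fold of the mean log ratios is smaller, that fold is given in its place. Such bounds are open to dye bias.

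Gene lists were tested with fry for change on balance in 1 direction, adjusted over 160 pairs of 20 pathway lists and 8 dose comparisons, with marker lists of other cell types adjusted apart over 80 pairs. Comparisons other than dose against control formed families of their own. Fry does not compare a list with other genes. Camera with an estimated correlation, which does, was the alternative, and a list call given with its fry p alone also passed there. Of 47 pathway calls 21 did, and of 7 marker calls 0. A list median is the median log2 change of its measured members, and some genes stand on more than 1 list. The neutrophil markers were not tested because fewer than 3 were measured. "With slide as a block" means a term for each slide in the fit, and "within slides" the range over the slides that held both groups.

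The named genes follow a rule. It takes Cyp1a1, Cyp1a2, Cyp1b1 and Cdkn1a in every group, and genes past the threshold whose dosed arrays all lie above or all below every control array. Of these it takes the 8 with the largest change each way at 300 mg/kg, 4 at 150 mg/kg and 3 at 50 and 5 mg/kg. It adds up to 4 members with the smallest adjusted p of each list past its test, the 4 largest each way for the difference between times at 300 mg/kg and for the controls, and the 3 largest each way for 300 against 150 mg/kg. Of list members the text gives examples. Some genes taken for their large change are described only with the flagged results or the effects of the processing, most of them because 1 array decided their call. A few other genes are not reported here and have no part in the tallies of named genes, but they stay in all other totals and in the lists. Groups, comparisons, gene and list tests, lists, the rule and the alternatives, except for those named as later choices, were fixed before the data were examined.

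Alternatives were other background corrections, Agilent's processed signals, median centring in place of loess, Aquantile between arrays, other probe filters, the mean of a gene's probes, the authors' values, slide or scan day or replicate number as a block, no intensity trend, only the groups compared, a fold of at least 1.5, and each array of a comparison left out in turn. Leaving out slide 7 and slide-aware splits were added after seeing the data. The fit was tested on simulated data. Over 8 dose comparisons it recovered 53.7 to 82.1, 95.5 to 100 and 98.5 to 100% of genes changed by 0.5, 1 and 2 (log2). False calls were 5 to 14 among 16240. Real arrays correlate within slides, so these rates may not hold there. Plots used matplotlib 3.10.9.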

Results

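Benzo(a)pyrene (BaP) is a polycyclic aromatic hydrocarbon that binds the aryl hydrocarbon receptor (AHR). CYP1 enzymes convert it to metabolites that react with DNA. The study asked how the liver of male mice of the B6C3F1 hybrid strain responds to it over a range of doses. Animals received 5, 50, 150 or 300 mg/kg BaP in corn oil by gavage on each of 3 days, and controls received corn oil alone. Livers were taken 4 h or 24 h after the last dose. Each 4 h group and the 24 h control group held 5 arrays and each dosed 24 h group held 4, which gave 46 arrays in 10 groups. Between 45.1 and 60.6% of the probes lay well above background in the liver channel. The median correlation of an array with the others of its group was between 0.966 and 0.985. In total 16240 genes or transcripts were tested, 10880 of them with a gene symbol, and the number of arrays per group limits the precision of every value.

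The first comparison asked what 300 mg/kg did 4 h after the last dose, with 5 arrays in each group. Genes that AHR controls rose together. Cyp1a1, a monooxygenase that oxidises BaP, was not well above background on the control arrays and was at least 83.7-fold higher (adjusted p = 1.47e-12). Cyp1b1, the related enzyme, was at least 5.41-fold higher (adjusted p = 1.41e-12) and Ahrr, the AHR repressor, at least 2.50-fold higher (adjusted p = 1.35e-12). The quinone reductase Nqo1 rose 9.12-fold (log2 change 3.19 ± 0.13). Ugdh, which makes the sugar donor of glucuronidation, rose 3.64-fold (1.87 ± 0.13). Of 12 measured AHR battery genes, 9 rose and 3 did not pass (9 up adjusted over the list alone). Their median log2 change was 1.63 (1.65 with slide as a block, 1.30 to 1.92 within slides), with fry adjusted p = 1.39e-20. Cyp1a2, the CYP1 gene most active in normal liver, was at -0.23 ± 0.16 with adjusted p = 0.369, and its probes went in opposite directions. With median centring in place of loess Cyp1a2 was at 0.81 and past the threshold.

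Genes of the antioxidant transcription factor NRF2 also rose at 300 mg/kg and 4 h. Of 24 measured NRF2 targets, 20 rose, 1 fell and 3 did not pass (20 up and 1 down adjusted over the list alone). Their median was 1.12 (1.15 with slide as a block, 0.92 to 1.35 within slides), with fry adjusted p = 3.63e-19. Among them were the carbonyl reductase Cbr3 (4.19 ± 0.17), the glutathione transferases Gsta1 (3.53 ± 0.27) and Gsta2 (3.09 ± 0.28) and the sulfiredoxin Srxn1 (2.81 ± 0.11). Targets of the nuclear receptors CAR and PXR rose too. Of 18 measured CAR and PXR targets, 12 rose and 6 did not pass (14 up adjusted over the list alone). The median was 0.72 (0.78 with slide as a block, 0.51 to 1.05 within slides), with fry adjusted p = 1.09e-07. Cyp2b10, the classic CAR target, rose 7.02-fold (2.81 ± 0.25), measured on 2 of 5 control arrays. Por, which passes electrons to cytochrome P450 enzymes, rose 3.78-fold (1.92 ± 0.20). Of 25 measured p53 targets, 9 rose and 16 did not pass (10 up adjusted over the list alone). Their median was 0.18 (0.24 with slide as a block, 0.14 to 0.39 within slides), with fry adjusted p = 1.11e-08. They included the cell cycle inhibitor Cdkn1a (2.49 ± 0.23), the p53 ubiquitin ligase Mdm2 (0.94 ± 0.081) and Trp53inp1 (1.45 ± 0.16). Of 16 measured glucocorticoid and fasting response genes, 14 rose and 2 did not pass (14 up adjusted over the list alone). The median was 1.55 (1.48 with slide as a block, 1.32 to 1.78 within slides), with fry adjusted p = 2.42e-10. The metallothionein Mt2 (3.03 ± 0.40) and the transcription factor Cebpd (1.94 ± 0.18) were among them.

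Genes that make fatty acids fell at the same dose and time. Of 19 measured fatty acid and triglyceride synthesis genes, 1 rose, 11 fell and 7 did not pass (1 up and 11 down adjusted over the list alone). Their median was -0.40 (-0.44 with slide as a block, -0.70 to -0.21 within slides), with fry adjusted p = 5.37e-06 and adjusted p = 0.158 from camera with an estimated correlation. Fasn, the fatty acid synthase, was 4.36-fold lower (-2.12 ± 0.24), and its regulator Srebf1 (-1.53 ± 0.15) and the elongase Elovl6 (-1.52 ± 0.22) fell as well. Of 21 measured interferon response genes, 1 rose, 14 fell and 6 did not pass (1 up and 16 down adjusted over the list alone). The median was -0.42 (-0.38 with slide as a block, -0.40 to -0.21 within slides), with fry adjusted p = 6.51e-06 and camera adjusted p = 0.145. The antiviral gene Rsad2 (-1.08 ± 0.18) and Ifit3 (-0.89 ± 0.11) were among those that fell. Of 14 measured heat shock genes, 7 rose and 7 did not pass (7 up adjusted over the list alone). Their median was 0.34 (0.37 with slide as a block, 0.37 to 0.55 within slides), with fry adjusted p = 0.0247 and camera adjusted p = 0.302. The inducible chaperone Hspa1a (1.32 ± 0.27) and its partner Bag3 (1.003 ± 0.20) rose. Some genes with higher expression in male than in female mouse liver fell. Of 17 measured male-predominant genes, 8 fell and 9 did not pass (10 down adjusted over the list alone). The median was -0.53 (-0.50 with slide as a block, -0.998 to -0.39 within slides), with fry adjusted p = 2.89e-04 and camera adjusted p = 0.303. They included Nudt7 (-1.15 ± 0.22), Cyp2u1 (-0.75 ± 0.16) and the steroid dehydrogenase Hsd3b5 (-1.91 ± 0.17), which was at 0.033 with the scanner's processed signals. Of 14 measured female-predominant genes, 4 rose and 10 did not pass (4 up adjusted over the list alone). Their median was 0.18 (0.21 with slide as a block, -0.059 to 0.60 within slides), with fry adjusted p = 0.00342 and camera adjusted p = 0.307. Among them Fmo2 (2.79 ± 0.26) and Cyp2b13 (2.99 ± 0.36) rose.

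Other large increases at 300 mg/kg and 4 h were those of the chaperone gene Hspa2 (3.12 ± 0.16) and the stress gene Gadd45g (3.27 ± 0.49). Large decreases included those of the steroid dehydrogenase Hsd3b4 (-2.85 ± 0.27), the clock output gene Dbp (-2.24 ± 0.43), the clock repressor Nr1d1 (-2.16 ± 0.31) and the lipoprotein lipase Lpl (-1.95 ± 0.24). Some markers of other liver cell types fell beside these groups. Of 12 measured Kupffer cell and macrophage markers, 6 fell and 6 did not pass (6 down adjusted over the list alone). The median was -0.66 (-0.57 with slide as a block, -1.14 to 0.064 within slides), with fry adjusted p = 0.0359 and camera adjusted p = 0.762. Of 12 measured stellate cell markers, 4 fell and 8 did not pass (5 down adjusted over the list alone). Their median was -0.44 (-0.40 with slide as a block, -0.64 to -0.15 within slides), with fry adjusted p = 0.0129 and camera adjusted p = 0.762. Of 4 measured B cell markers, 2 fell and 2 did not pass (3 down adjusted over the list alone). The median was -0.32 (-0.28 with slide as a block, -0.56 to -0.081 within slides), with fry adjusted p = 4.26e-04 and camera adjusted p = 0.654. In all, 3177 genes passed, 1033 up and 2144 down. For 1816 of them no dosed array overlapped any control array. Chance gives such a separation to 0.794% of unchanged genes. The 1816 cannot be set against that rate, because the same arrays gave their calls. The share of increases was 32.5%, against 44.1% with the authors' values and 73.0% of 1266 genes with median centring in place of loess. Median centring also ended the calls of Adgre1, Csf1r, Colec11, Pdgfrb, Blnk, Cd79b, Oasl1 and Acly. The count was 4250 with slide as a block and 4085 with scan day as a block. Of the 3177 changes, 2920 had the same sign within each of the 4 slides that held both groups.

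**Figure D1:**
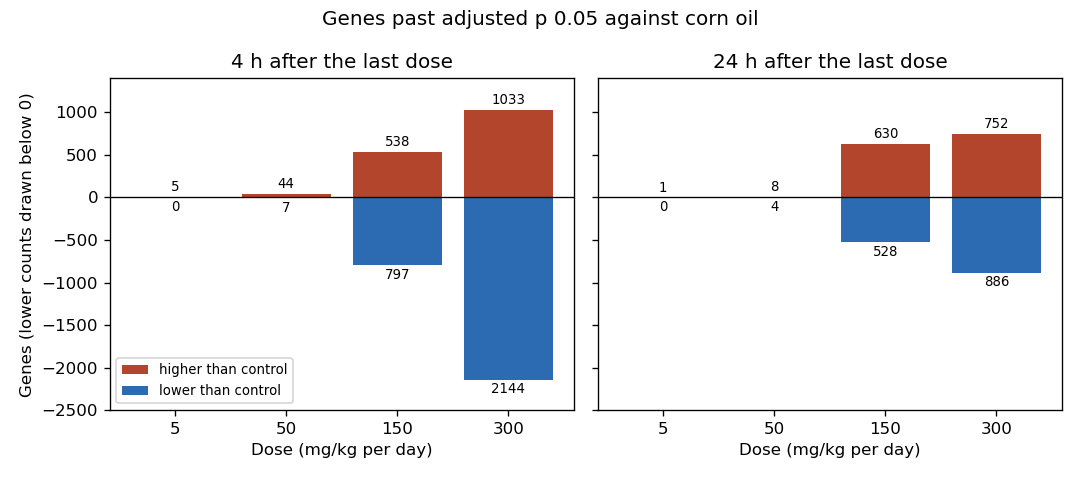
Number of genes past adjusted p 0.05 against corn oil controls, by dose in mg/kg per day (horizontal axis) and by time after the last dose (4 h left, 24 h right), with higher genes drawn above 0 and lower genes below 0. At 300 mg/kg 1033 genes were higher and 2144 lower at 4 h, and 752 higher and 886 lower at 24 h.

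At 150 mg/kg and 4 h, with 5 arrays in each group, AHR genes rose as well. Cyp1a1 was at least 88.0-fold higher than in controls (adjusted p = 4.42e-12) and Cyp1b1 at least 1.95-fold higher (adjusted p = 8.45e-04). Of 12 measured AHR battery genes, 9 rose and 3 did not pass (9 up adjusted over the list alone). Their median was 1.04 (1.07 with slide as a block, 1.01 to 1.05 within slides), with fry adjusted p = 2.49e-16. Of 24 measured NRF2 targets, 15 rose and 9 did not pass (17 up and 1 down adjusted over the list alone). The median was 0.79 (0.79 with slide as a block, 0.61 to 0.80 within slides), with fry adjusted p = 1.40e-13. Among these, Nqo1 (2.22 ± 0.13), Cbr3 (2.002 ± 0.17) and Srxn1 (1.89 ± 0.11) rose. The monooxygenase Fmo2 (2.58 ± 0.26) and the olfactory receptor gene Olfr114 (2.90 ± 0.25) had large increases too. Of 18 measured CAR and PXR targets, 6 rose and 12 did not pass (10 up and 1 down adjusted over the list alone). Their median was 0.43 (0.49 with slide as a block, 0.41 to 0.66 within slides), with fry adjusted p = 3.68e-04. Por was 3.12-fold higher (1.64 ± 0.20). Of 16 measured glucocorticoid and fasting response genes, 6 rose and 10 did not pass (10 up adjusted over the list alone). The median was 0.71 (0.73 with slide as a block, 0.40 to 0.995 within slides), with fry adjusted p = 2.48e-04. They included Cebpd (0.98 ± 0.18) and Tsc22d3 (0.93 ± 0.16). Of 25 measured p53 targets, 5 rose and 20 did not pass (7 up adjusted over the list alone). Their median was 0.099 (0.11 with slide as a block, 0.046 to 0.080 within slides), with fry adjusted p = 0.00738 and camera adjusted p = 0.0887. Mdm2 was at 0.56 ± 0.081 and past the threshold, while Cdkn1a was at 0.70 ± 0.23 and missed it (adjusted p = 0.0539).

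Some lipid synthesis genes fell at 150 mg/kg and 4 h. Of 24 measured cholesterol synthesis genes, 1 rose, 5 fell and 18 did not pass (1 up and 9 down adjusted over the list alone). The median was -0.31 (-0.34 with slide as a block, -0.41 to -0.057 within slides), with fry adjusted p = 0.0175 and camera adjusted p = 0.369. Hmgcs1, an early enzyme of the pathway, was 2.73-fold lower (-1.45 ± 0.25). Of 19 measured fatty acid and triglyceride synthesis genes, 5 fell and 14 did not pass (10 down adjusted over the list alone). Their median was -0.26 (-0.28 with slide as a block, -0.41 to -0.14 within slides), with fry adjusted p = 6.00e-04 and camera adjusted p = 0.155. Fasn was 2.99-fold lower (-1.58 ± 0.24). Of 21 measured interferon response genes, 9 fell and 12 did not pass (11 down adjusted over the list alone). The median was -0.26 (-0.26 with slide as a block, -0.32 to -0.20 within slides), with fry adjusted p = 4.81e-04 and camera adjusted p = 0.136. Of 14 measured heat shock genes, 3 rose and 11 did not pass (4 up adjusted over the list alone). Their median was 0.29 (0.27 with slide as a block, 0.036 to 0.40 within slides), with fry adjusted p = 0.0443 and camera adjusted p = 0.223. Of 14 measured female-predominant genes, 5 rose and 9 did not pass (5 up adjusted over the list alone). The median was 0.14 (0.20 with slide as a block, 0.079 to 0.43 within slides), with fry adjusted p = 0.00975 and camera adjusted p = 0.201. The clock genes Dbp (-1.89 ± 0.43) and Nr1d1 (-1.85 ± 0.31) fell. Of 4 measured B cell markers, 1 fell and 3 did not pass (2 down adjusted over the list alone). Their median was -0.32 (-0.23 with slide as a block, -0.28 to -0.071 within slides), with fry adjusted p = 0.00792 and camera adjusted p = 0.654. Over all genes 1335 passed, 538 up and 797 down. The share of increases was 40.3%, and with median centring in place of loess it was 89.6% of 771 genes. With that centring Srebf1, Sc5d, Stard4, Msmo1, Elovl5, Elovl6, Ifit3, Irf7, Psmb9 and Blnk were no longer past the threshold. The count was 1876 with slide as a block and 1724 with scan day as a block. Of the 1335 changes, 1311 had the same sign within each of the 3 slides that held both groups.

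The low doses at 4 h ask how little BaP still gives a response. At 50 mg/kg, with 5 arrays in each group, Cyp1a1 was at least 67.0-fold higher than in controls (adjusted p = 1.65e-10). Cyp1b1 (adjusted p = 0.967) and Cdkn1a (-0.076 ± 0.23) did not pass. Olfr114 rose 6.25-fold (2.64 ± 0.25), with adjusted p = 0.161 from the processed signals. Slc46a3, a lysosomal transporter gene, rose 2.56-fold (1.35 ± 0.13). Of 12 measured AHR battery genes, 6 rose and 6 did not pass (7 up adjusted over the list alone). The median was 0.49 (0.46 with slide as a block, 0.44 to 0.62 within slides), with fry adjusted p = 1.19e-08. Of 24 measured NRF2 targets, 5 rose and 19 did not pass (10 up adjusted over the list alone). Their median was 0.30 (0.33 with slide as a block, 0.19 to 0.46 within slides), with fry adjusted p = 5.45e-05. Nqo1 rose 1.85-fold (0.89 ± 0.13), and Ugdh (0.88 ± 0.13), Akr1b8 (0.78 ± 0.11) and Srxn1 (0.69 ± 0.11) rose as well. Of the 51 genes past the threshold 44 were up and 7 down (86.3% up, and 97.3% with median centring). When only the arrays compared were fitted, 26 passed. The count was 37 with slide as a block and 45 with scan day as a block. It was 32 without 4 h control replicate 1 or 50 mg/kg 4 h replicate 5, 30 without 50 mg/kg 4 h replicate 3 and 29 without 50 mg/kg 4 h replicate 4. All 51 changes had the same sign within each of the 3 slides that held both groups.

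At 5 mg/kg and 4 h, again with 5 arrays in each group, Cyp1a1 was at least 14.9-fold higher (adjusted p = 4.11e-06). Its log2 ratio on dosed replicate 4 was 0.53, near the controls, against 4.05 to 5.84 on the other dosed arrays. Without that array Cyp1a1 still passed. Olfr114 rose 3.95-fold (1.98 ± 0.25), with adjusted p = 1.000 from the processed signals, and Slc46a3 rose 2.12-fold (1.09 ± 0.13). Adgrg3 (0.74 ± 0.14) and Htatip2 (0.63 ± 0.12), 2 genes outside the rule for named genes and chosen after their values were seen, completed the 5 genes past the threshold, all up. Of 12 measured members of the AHR battery, 1 rose and 11 did not pass (2 up adjusted over the list alone). The median was 0.16 (0.10 with slide as a block, 0.023 to 0.18 within slides), with fry adjusted p = 0.0128. Nqo1 was at 0.30 ± 0.13 and Ugdh at 0.43 ± 0.13. The count was 5 with slide as a block and 6 with scan day as a block. It was 3 without 4 h control replicate 1 or 5 or 5 mg/kg 4 h replicate 1 or 2 or 3 and 8 without 5 mg/kg 4 h replicate 4. All 5 changes had the same sign within each of the 3 slides that held both groups. When only these 10 arrays were fitted with limma it was 0, with 417 genes at an unadjusted p under 0.05 and adjusted p = 0.840 for Cyp1a1.

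**Figure D2:**
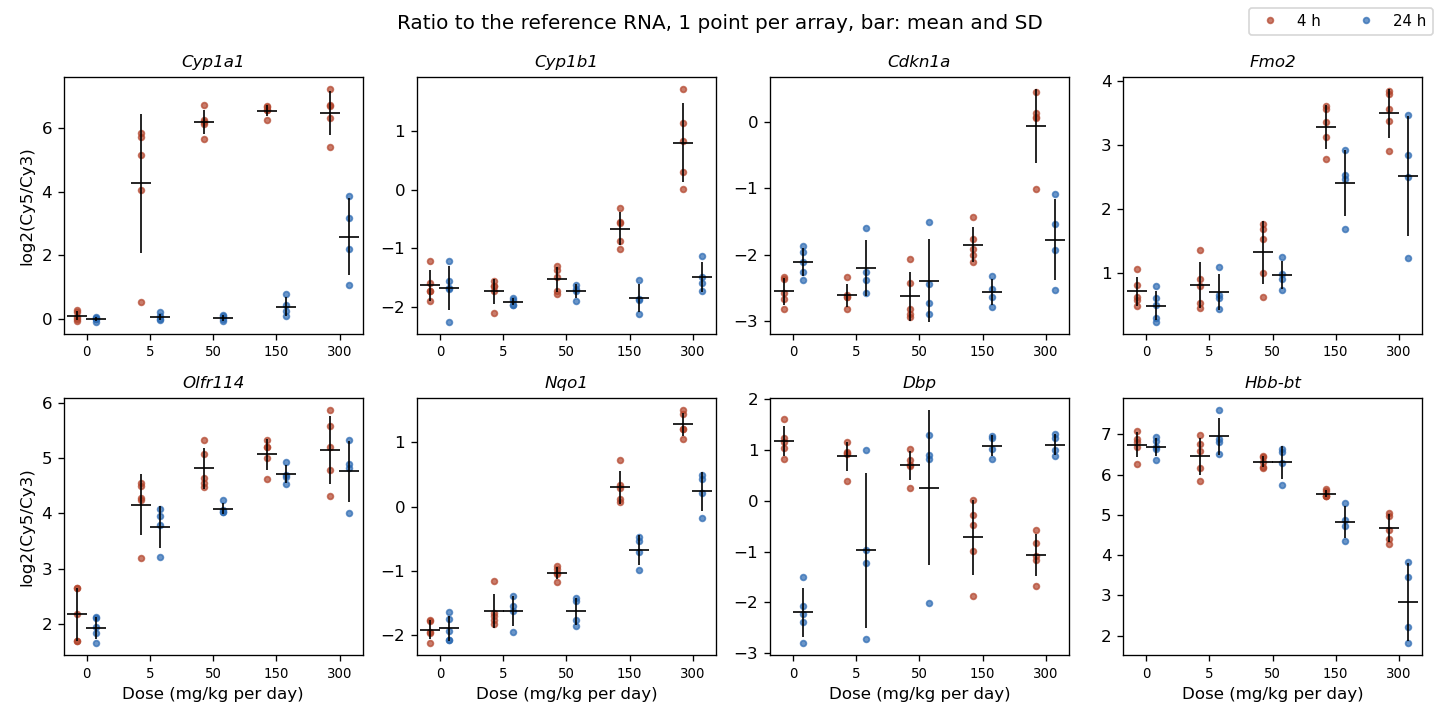
log2 of the Cy5 to Cy3 ratio (vertical axes) for 8 genes by dose in mg/kg per day (horizontal axes), with 1 point per array, 4 h in red and 24 h in blue, and the mean with SD as a bar. At 4 h Cyp1a1 was at least 14.9-fold above its controls at 5 mg/kg, where 1 of 5 arrays lay near the controls, and at least 83.7-fold at 300 mg/kg, while Hbb-bt fell by a log2 change of 3.86 at 300 mg/kg and 24 h (-0.19 with the processed signals).

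Across the 5 groups at 4 h, 4154 genes had a trend with the rank of the dose, 1346 up and 2808 down. Of 12 measured members of the AHR battery, 9 rose and 3 did not pass (9 up adjusted over the list alone). Their median was 1.76, with fry adjusted p = 1.10e-22. Of 24 measured targets of NRF2, 20 rose, 2 fell and 2 did not pass (20 up and 2 down adjusted over the list alone). The median was 1.14, with fry adjusted p = 4.55e-21. The share of increases among trend genes was 32.4%, 42.9% with the processed signals and 77.3% of 2154 genes with median centring. Between 150 and 300 mg/kg at 4 h, 199 genes differed, 90 higher and 109 lower at 300 mg/kg, with 5 arrays in each group. Cbr3 was 4.57-fold higher at 300 than at 150 mg/kg (2.19 ± 0.17), Cdkn1a 3.45-fold higher (1.79 ± 0.23) and Mt2 4.07-fold higher (2.02 ± 0.40). Of 24 measured targets of NRF2, 8 were higher and 16 did not pass (14 up and 1 down adjusted over the list alone). Their median was 0.38, with fry adjusted p = 8.00e-07. Of 25 measured p53 targets, 4 were higher and 21 did not pass (7 up adjusted over the list alone). The median was 0.16, with fry adjusted p = 9.26e-05. The count of 199 became 254 with slide as a block, 352 with it as a random block and 54 with median centring. It was 106 without 150 mg/kg 4 h replicate 5, 92 without 150 mg/kg 4 h replicate 3, 124 without 300 mg/kg 4 h replicate 5, 89 without 150 mg/kg 4 h replicate 2 and 73 without 300 mg/kg 4 h replicate 2.

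The next comparisons asked what the liver showed 24 h after the last dose, with 4 arrays in each dosed group and 5 controls. At 300 mg/kg circadian clock genes changed. Of 18 measured clock genes, 10 rose, 3 fell and 5 did not pass (11 up and 3 down adjusted over the list alone). Their median was 0.91 (0.91 with slide as a block, 0.83 to 1.20 within slides), with fry adjusted p = 2.47e-05. The clock output gene Dbp was 9.84-fold higher (3.30 ± 0.46, adjusted p = 2.31e-06), and Tef (2.07 ± 0.23) and Usp2 (2.87 ± 0.37), the latter measured on 2 of 5 control arrays, rose. Arntl, which encodes the core activator BMAL1, was 4.42-fold lower (-2.15 ± 0.28). Of 24 measured NRF2 targets, 14 rose, 2 fell and 8 did not pass (15 up and 3 down adjusted over the list alone). The median was 0.61 (0.64 with slide as a block, 0.65 to 0.70 within slides), with fry adjusted p = 7.90e-09. Nqo1 was 4.38-fold higher (2.13 ± 0.14), and Gsta1 (3.17 ± 0.29) and Gstm1 (1.70 ± 0.15) rose. Of 12 measured AHR battery genes, 5 rose, 1 fell and 6 did not pass (7 up and 1 down adjusted over the list alone). Their median was 0.38 (0.38 with slide as a block, 0.48 to 0.53 within slides), with fry adjusted p = 2.04e-09. Cyp1a1 was at least 5.89-fold higher (adjusted p = 0.00104). Cyp1b1 was well above background on 1 of the 4 dosed arrays, and Cdkn1a was at 0.34 ± 0.25, not past the threshold. Of 25 measured p53 targets, 6 rose and 19 did not pass (7 up adjusted over the list alone). The median was 0.17 (0.17 with slide as a block, 0.087 to 0.31 within slides), with fry adjusted p = 1.34e-05. The cyclin Ccng1 (1.12 ± 0.13) was among them. Of 26 measured DNA repair genes, 6 rose, 1 fell and 19 did not pass (6 up and 1 down adjusted over the list alone). Their median was 0.095 (0.073 with slide as a block, 0.0040 to 0.14 within slides), with fry adjusted p = 2.47e-05. Brca1, which acts in homologous recombination, was 1.83-fold higher (0.87 ± 0.14).

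Some cholesterol synthesis genes rose at 300 mg/kg and 24 h. Of 24 measured cholesterol synthesis genes, 10 rose and 14 did not pass (16 up and 1 down adjusted over the list alone). The median was 0.47 (0.55 with slide as a block, 0.46 to 0.77 within slides), with fry adjusted p = 0.00439 and camera adjusted p = 0.158. Of 18 measured CAR and PXR targets, 9 rose, 2 fell and 7 did not pass (11 up and 2 down adjusted over the list alone). Their median was 0.60 (0.68 with slide as a block, 0.77 to 0.84 within slides), with fry adjusted p = 1.58e-04 and camera adjusted p = 0.0778. Of 16 measured glucocorticoid and fasting response genes, 7 rose and 9 did not pass (7 up adjusted over the list alone). The median was 0.30 (0.43 with slide as a block, 0.36 to 0.99 within slides), with fry adjusted p = 6.00e-04 and camera adjusted p = 0.0947. The metallothionein Mt1 was 6.73-fold higher (2.75 ± 0.34). Of 17 measured male-predominant genes, 12 fell and 5 did not pass (12 down adjusted over the list alone). Their median was -0.78 (-0.69 with slide as a block, -0.70 to -0.31 within slides), with fry adjusted p = 1.63e-04 and camera adjusted p = 0.0869. The elongase Elovl3 (-3.15 ± 0.30) was one of these, and Hsd3b5 (-0.79 ± 0.18) was at 0.17 with the processed signals. Of 14 measured female-predominant genes, 7 rose, 3 fell and 4 did not pass (9 up and 3 down adjusted over the list alone). The median was 0.58 (0.58 with slide as a block, 0.40 to 1.097 within slides), with fry adjusted p = 0.0134 and camera adjusted p = 0.339. Of 20 measured endoplasmic reticulum stress genes, 6 fell and 14 did not pass (1 up and 9 down adjusted over the list alone). Their median was -0.32 (-0.29 with slide as a block, -0.51 to -0.18 within slides), with fry adjusted p = 0.00129 and camera adjusted p = 0.158. Of 14 measured heat shock genes, 4 fell and 10 did not pass (7 down adjusted over the list alone). The median was -0.35 (-0.33 with slide as a block, -0.70 to 0.026 within slides), with fry adjusted p = 0.0140 and camera adjusted p = 0.303. The chaperone Hspa1b (-1.34 ± 0.28) fell. Of 21 measured interferon response genes, 3 fell and 18 did not pass (7 down adjusted over the list alone). Their median was -0.22 (-0.24 with slide as a block, -0.34 to -0.13 within slides), with fry adjusted p = 0.0432 and camera adjusted p = 0.405. The antiviral gene Rsad2 (-1.08 ± 0.20), measured on 3 of 4 dosed arrays, fell again. Median centring in place of loess ended the calls of Atf5, Hspa5, Pdia6, Sdf2l1, Bag3, Hsph1, Ifit3 and Isg15.

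Globin genes fell at 300 mg/kg and 24 h. Hbb-bt, a beta globin gene, was 14.5-fold lower (-3.86 ± 0.27, adjusted p = 7.45e-14), although it was at -0.19 with the processed signals, which leaves that fold open. Hba-a1, an alpha globin gene, was 9.05-fold lower (-3.18 ± 0.23). At 300 mg/kg and 4 h Hbb-bt (-2.08 ± 0.25) had fallen too, at -0.39 (adjusted p = 0.430) with the processed signals. Outside the rule, and seen before they were chosen, were the decreases of Hba-a1 (-1.78 ± 0.21) there and of Hbb-bt (-1.22 ± 0.25) and Hba-a1 (-0.93 ± 0.21) at 150 mg/kg and 4 h, the pair at 150 mg/kg without a call from the processed signals (adjusted p = 0.837 and 0.295). Of 5 measured erythroid markers, 3 fell and 2 did not pass (1 up and 3 down adjusted over the list alone). The median was -0.47 (-0.51 with slide as a block, -0.47 to -0.27 within slides), with fry adjusted p = 2.57e-08 and camera adjusted p = 0.299. The haem synthesis gene Alas2 (-0.53 ± 0.14) was at 0.016 with the processed signals and had adjusted p = 0.0585 without 300 mg/kg 24 h replicate 1. Of 4 measured adipocyte markers, 1 fell and 3 did not pass (2 down adjusted over the list alone). Their median was -0.31 (-0.35 with slide as a block, -0.31 to -0.018 within slides), with fry adjusted p = 0.0162 and camera adjusted p = 0.654. The decrease was that of the lipoprotein lipase Lpl (-1.79 ± 0.26). Other large increases were those of the lipid transporter gene Mfsd2a (3.05 ± 0.41), Olfr114 (2.83 ± 0.26) and the acute phase gene Orm3 (2.90 ± 0.43), measured on 1 of 5 control arrays. Decreases included Spon2 (-2.19 ± 0.25) and Serpina9 (-2.33 ± 0.36). In total 1638 genes passed, 752 up and 886 down. For 1165 the dosed and control arrays did not overlap. Chance gives this to 1.59% of unchanged genes, a rate that does not hold for genes called on the same arrays. The share of increases was 45.9%, 56.8% without background correction and 84.4% of 926 genes with median centring. The count was 2216 with slide as a block and 2126 with scan day as a block. Of the 1638 changes, 1583 had the same sign within each of the 3 slides that held both groups.

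At 150 mg/kg and 24 h, with 4 dosed and 5 control arrays, clock genes changed as well. Of 18 measured clock genes, 11 rose, 3 fell and 4 did not pass (12 up and 3 down adjusted over the list alone). The median was 0.87 (0.87 with slide as a block, 0.57 to 0.88 within slides), with fry adjusted p = 8.63e-06. Dbp was 9.71-fold higher (3.28 ± 0.46, adjusted p = 5.15e-06) and Arntl 4.65-fold lower (-2.22 ± 0.28). Of 12 measured AHR battery genes, 4 rose, 1 fell and 7 did not pass (4 up and 1 down adjusted over the list alone). Their median was 0.29 (0.29 with slide as a block, 0.19 to 0.25 within slides), with fry adjusted p = 2.12e-04 and camera adjusted p = 0.0809. Cyp1a1 was well above background on 2 of the 4 dosed arrays (adjusted p = 0.755) and passed with the processed signals (adjusted p = 0.00532). Of 24 measured NRF2 targets, 8 rose, 2 fell and 14 did not pass (9 up and 4 down adjusted over the list alone). The median was 0.21 (0.24 with slide as a block, 0.20 to 0.25 within slides), with fry adjusted p = 0.00129 and camera adjusted p = 0.155. Both Nqo1 (1.22 ± 0.14) and Gsta1 (2.19 ± 0.29) rose. Of 18 measured CAR and PXR targets, 6 rose, 1 fell and 11 did not pass (7 up and 1 down adjusted over the list alone). Their median was 0.46 (0.50 with slide as a block, 0.21 to 0.47 within slides), with fry adjusted p = 0.00342 and camera adjusted p = 0.158. Por was 4.26-fold higher (2.09 ± 0.22). Of 16 measured glucocorticoid and fasting response genes, 5 rose and 11 did not pass (5 up and 1 down adjusted over the list alone). The median was 0.30 (0.36 with slide as a block, 0.12 to 0.43 within slides), with fry adjusted p = 0.0390 and camera adjusted p = 0.339. The metallothionein Mt2 (2.61 ± 0.42) was one of them. Of 14 measured female-predominant genes, 4 rose and 10 did not pass (5 up adjusted over the list alone). Their median was 0.38 (0.41 with slide as a block, -0.080 to 0.55 within slides), with fry adjusted p = 0.0194 and camera adjusted p = 0.303. Of 20 measured endoplasmic reticulum stress genes, 2 fell and 18 did not pass (3 down adjusted over the list alone). The median was -0.17 (-0.12 with slide as a block, -0.095 to -0.085 within slides), with fry adjusted p = 0.0443 and camera adjusted p = 0.369. Of 5 measured erythroid markers, 1 rose, 2 fell and 2 did not pass (1 up and 2 down adjusted over the list alone). Their median was -0.21 (-0.24 with slide as a block, -0.24 to -0.20 within slides), with fry adjusted p = 0.00581 and camera adjusted p = 0.654. Hba-a1 was 3.28-fold lower (-1.71 ± 0.23).

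Large single changes at 150 mg/kg and 24 h were the decrease of Spon2 (-2.21 ± 0.25) and the increases of Olfr114 (2.77 ± 0.26) and of Usp2 (2.89 ± 0.37), measured on 2 of 5 control arrays. The elongase Elovl3 (-2.58 ± 0.30) fell too, with adjusted p = 0.715 from the processed signals. The threshold was passed by 1158 genes, 630 up and 528 down. The share of increases was 54.4%, 65.6% with the processed signals and 97.9% of 4094 genes with median centring. The count was 1303 with slide as a block and 1251 with scan day as a block. It was 555 without 150 mg/kg 24 h replicate 4 and 699 without 150 mg/kg 24 h replicate 3, and 1760 with the authors' values. Of the 1158 changes, 1106 had the same sign within each of the 2 slides that held both groups.

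At 50 mg/kg and 24 h, with 4 dosed and 5 control arrays, clock genes were again among those that changed. Of 18 measured clock genes, 2 rose, 2 fell and 14 did not pass (12 up and 3 down adjusted over the list alone). The median was 0.65 (0.55 with slide as a block, 0.14 to 0.68 within slides), with fry adjusted p = 9.86e-04. The clock output gene Tef was 2.76-fold higher (1.47 ± 0.23, adjusted p = 0.00163) and Dbp 5.46-fold higher (2.45 ± 0.46), and Arntl was 2.52-fold lower (-1.33 ± 0.28). Olfr114 rose 4.46-fold (2.16 ± 0.26), with adjusted p = 0.335 from the processed signals. Cyp1a1 and Cyp1b1 were not well above background in either group, and Cdkn1a was at -0.28 ± 0.25. None of 20 measured endoplasmic reticulum stress genes passed the gene test (0 adjusted over the list alone). Their median was -0.25 (-0.21 with slide as a block, -0.47 to -0.016 within slides), with fry adjusted p = 0.0368 and camera adjusted p = 0.0713. The 12 genes past the threshold were 8 up and 4 down (66.7% up, and 100% of 4 with median centring), and 1 gene passed when only these 9 arrays were fitted. The count was 10 with slide as a block and 15 with scan day as a block. It was 3 without 50 mg/kg 24 h replicate 1, 2 without 50 mg/kg 24 h replicate 3 or 4 or 24 h control replicate 2 or 4 and 46 without 50 mg/kg 24 h replicate 2. Of the 12 changes, 11 had the same sign within each of the 3 slides that held both groups. Dbp on dosed replicate 2 lay among the controls, and without that array its log2 change was 3.21. It had adjusted p = 0.0703 with slide as a block, and 0.0876 and 0.0652 without 24 h control replicate 2 and 4 in turn and 0.0982, 0.293 and 0.157 without 50 mg/kg 24 h replicate 1, 3 and 4 in turn. Arntl had adjusted p = 0.0625 with the processed signals and 0.116 with slide as a block, and 0.0659, 0.116, 0.109, 0.120 and 0.0610 without 24 h control replicate 1, 2, 3, 4 and 5 in turn and 0.209, 0.534 and 0.166 without 50 mg/kg 24 h replicate 1, 3 and 4 in turn.

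At 5 mg/kg and 24 h only Olfr114 passed, 3.54-fold higher (1.82 ± 0.26, adjusted p = 3.67e-04, 4 dosed and 5 control arrays). With the processed signals its adjusted p was 0.985 and limma found 0 genes, with 745 at an unadjusted p under 0.05. Both stress lists were lower. All 24 h doses share these controls, where both lists exceeded 4 h controls, so high controls and a dose effect cannot be told apart. None of 14 measured heat shock and 20 endoplasmic reticulum stress genes passed (6 and 2 down adjusted over the list alone). The medians were -0.41 (-0.29 with slide as a block, -0.73 to -0.17 within slides) and -0.23 (-0.15, -0.32 to -0.17). Fry gave adjusted p = 0.0204 and 0.0390. Hspa8 was at -0.57 ± 0.18 and Hspa5 at -0.69 ± 0.23. Cyp1a1 and Cyp1b1 were not well above background in either group. With slide or scan day as a block 1 gene passed, and 3 without 24 h control replicate 1. Olfr114 rose on each of the 3 shared slides.

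**Figure D3:**
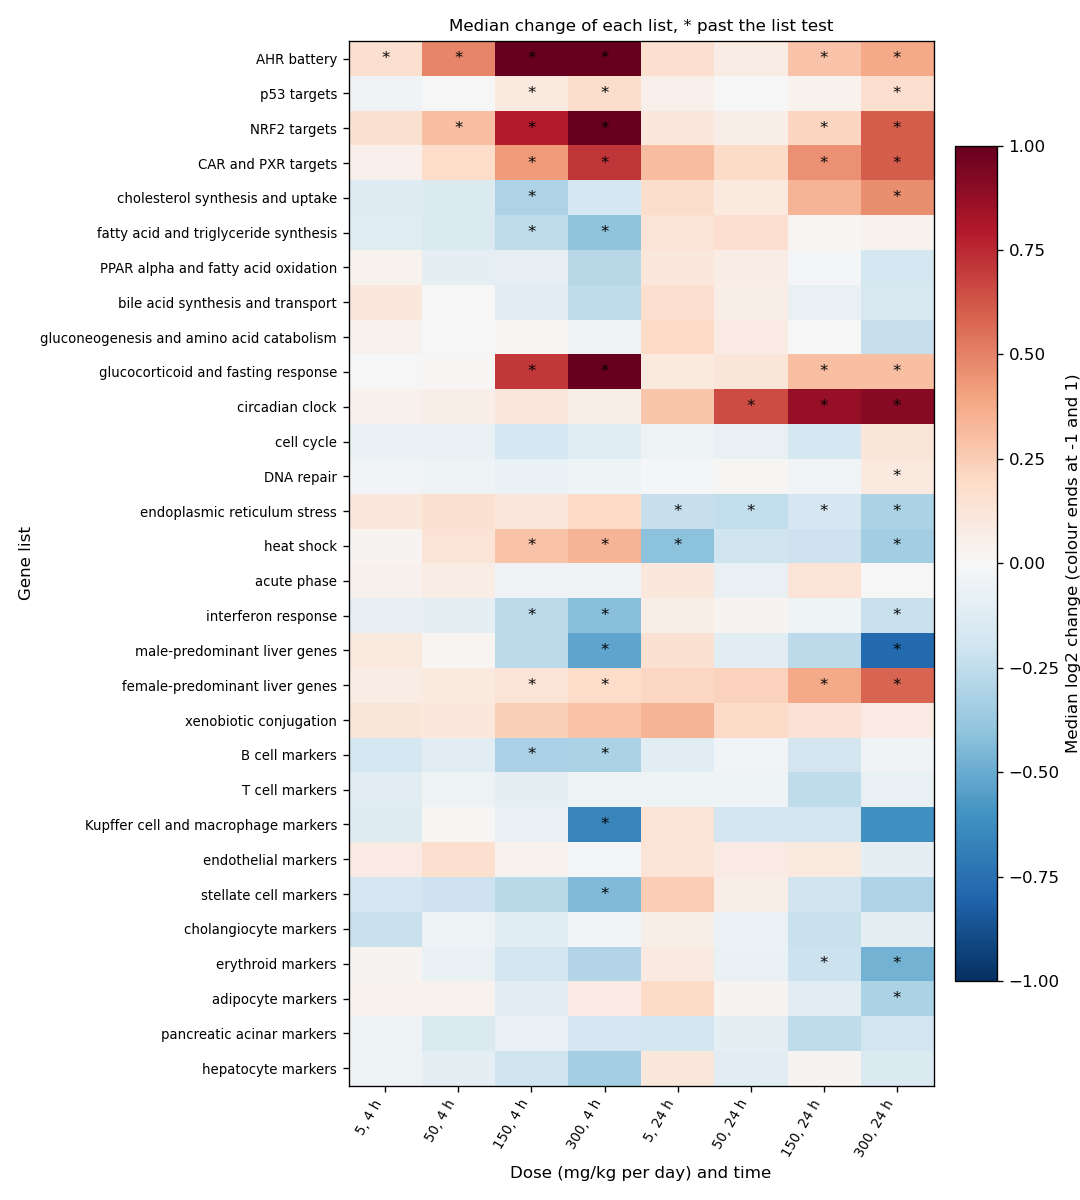
Median log2 change of each fixed gene list (vertical axis) at each dose in mg/kg per day and time (horizontal axis), as a colour scale whose ends stand for -1 and 1, with an asterisk where fry passed. The AHR battery had medians of 1.63 at 300 mg/kg and 4 h and 0.38 at 300 mg/kg and 24 h, and the clock list 0.057 and 0.91.

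At 24 h, 2543 genes had a dose trend, 1085 up and 1458 down (42.7% up, 52.9% with the processed signals and 93.1% with median centring). Of 18 measured clock genes, 11 rose, 3 fell and 4 did not pass (12 up and 3 down adjusted over the list alone). The median was 0.92, with fry adjusted p = 1.36e-06. Of 17 measured male-predominant genes, 12 fell and 5 did not pass (12 down adjusted over the list alone). Their median was -0.74, with fry adjusted p = 9.70e-06 and camera adjusted p = 0.0717. Between 150 and 300 mg/kg at 24 h, 12 genes differed, 9 higher and 3 lower at 300 mg/kg, with 4 arrays in each group. Globin genes were lower at the higher dose, Hba-a1 2.76-fold (-1.47 ± 0.24) and Hbb-bt 3.96-fold (-1.99 ± 0.28), the latter at -0.71 (adjusted p = 0.627) with the processed signals, and the glutathione peroxidase Gpx2 (1.04 ± 0.17) was higher. Of 5 measured erythroid markers, 1 was lower and 4 did not pass (1 down adjusted over the list alone). The median was -0.21, with fry adjusted p = 0.00262 and camera adjusted p = 0.217. Of 24 measured targets of NRF2, 3 were higher and 21 did not pass (9 up adjusted over the list alone). Their median was 0.27, with fry adjusted p = 9.63e-04. None of 26 measured DNA repair genes passed the gene test (3 up and 1 down adjusted over the list alone). The median was 0.13, with fry adjusted p = 2.34e-05. Of 23 measured cell cycle genes, 1 was higher and 22 did not pass (12 up adjusted over the list alone). Their median was 0.34, with fry adjusted p = 0.00148. The count of 12 became 26 with slide as a block and 1 with only the 8 arrays fitted. It was 20 without 300 mg/kg 24 h replicate 2, 22 without 300 mg/kg 24 h replicate 1, 7 without 300 mg/kg 24 h replicate 3 and 6 without 150 mg/kg 24 h replicate 3.

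Whether the effect of a dose differed between 24 h and 4 h was tested directly. At 300 mg/kg it differed for 1382 genes, with 835 more positive and 547 more negative at 24 h. The effect on Dbp was 5.54 ± 0.63 more positive at 24 h (adjusted p = 6.86e-08), and that on Fasn was 2.52 ± 0.35 more positive. More negative at 24 h were the effects on Cbr3 (-3.25 ± 0.24), Gadd45g (-3.45 ± 0.71) and Arntl (-3.10 ± 0.38). Groups differed between times as well. Of 12 measured members of the AHR battery, 7 were lower and 5 did not pass (7 down adjusted over the list alone). The median was -0.96, with fry adjusted p = 8.21e-09. Of 14 measured heat shock genes, 7 were lower and 7 did not pass (7 down adjusted over the list alone). Their median was -0.68, with fry adjusted p = 5.79e-04. Of 24 measured cholesterol synthesis genes, 8 were higher and 16 did not pass (15 up adjusted over the list alone). The median was 0.60, with fry adjusted p = 0.00223 and camera adjusted p = 0.158. At 150 mg/kg 591 genes differed between times, 375 more positive and 216 more negative at 24 h. Of 12 measured members of the AHR battery, 6 were lower and 6 did not pass (7 down adjusted over the list alone). Their median was -0.81, with fry adjusted p = 1.72e-07. The 4 h and 24 h comparisons share no arrays. At 300 mg/kg 258 genes rose at both times, against 47.8 for independent lists, 437 fell at both, against 117, and 120 went opposite ways, against 156. With median centring 303 genes differed between times at 300 mg/kg and 131 at 150 mg/kg, and with slide as a block 1989 and 866. The 150 mg/kg count was 382 without 150 mg/kg 24 h replicate 4.

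Control livers at 24 h and 4 h, 5 arrays each, differed too. Only slide 7 held both, so time and slide can hardly be told apart. Dbp was 10.3-fold lower at 24 h than at 4 h (-3.37 ± 0.43, adjusted p = 5.21e-06), and the metallothioneins Mt1 (-2.03 ± 0.32) and Mt2 (-2.49 ± 0.40) were lower. Higher at 24 h were Arntl (1.84 ± 0.26), Chka (1.76 ± 0.26) and Ppp1r3b (1.58 ± 0.27). Of 18 measured clock genes, 3 were higher, 8 were lower and 7 did not pass (4 up and 9 down adjusted over the list alone). The median was -0.46, with fry adjusted p = 0.00233 and camera adjusted p = 0.0704. Of 30 measured PPAR alpha and fatty acid oxidation genes, 7 were lower and 23 did not pass (1 up and 9 down adjusted over the list alone). Their median was -0.27, with fry adjusted p = 0.00481 and camera adjusted p = 0.0797. Of 20 measured endoplasmic reticulum stress genes, 6 were higher and 14 did not pass (10 up and 1 down adjusted over the list alone). The median was 0.36, with fry adjusted p = 2.90e-04. Of 14 measured heat shock genes, 6 were higher and 8 did not pass (7 up adjusted over the list alone). Their median was 0.47, with fry adjusted p = 0.00190. In all 426 genes differed, 204 higher and 222 lower at 24 h (47.9% higher). The count was 82 (64.6% higher) with median centring, 121 with slide and 1006 with scan day as a block. It was 264 and 252 without 24 h control replicate 4 and 2 in turn and 265 without 4 h control replicate 4.

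Across the 8 dose comparisons 47 of 160 pairs of a pathway list and a comparison passed fry, and 21 of these passed camera with an estimated correlation. Of the marker lists 7 of 80 pairs passed fry and 0 passed camera. The median of a pathway call kept its sign with slide as a block in 47 cases and on every shared slide in 44. Among marker calls it did so in 7 and 6. Pathway lists that passed fry in 0 of the 8 comparisons follow with the range of their median log2 change and the smallest adjusted p. They were PPAR alpha and fatty acid oxidation (-0.28 to 0.12, 0.101), bile acid synthesis and transport (-0.26 to 0.17, 0.173), gluconeogenesis and amino acid catabolism (-0.23 to 0.20, 0.244), cell cycle (-0.18 to 0.12, 0.0637), acute phase (-0.071 to 0.14, 0.493) and xenobiotic conjugation (0.085 to 0.34, 0.0721). In the same order, 1, 0, 0, 2, 0 and 3 of the 8 had an unadjusted fry p under 0.05, 4, 1, 1, 2, 1 and 4 passed fry for change in either direction, and camera passed none. Marker lists without a call were T cell markers (-0.25 to -0.044, 0.277), endothelial markers (-0.101 to 0.16, 0.432), cholangiocyte markers (-0.22 to 0.059, 0.129), pancreatic acinar markers (-0.25 to -0.054, 0.247) and hepatocyte markers (-0.34 to 0.12, 0.386). For these 0, 0, 1, 1 and 0 of 8 had an unadjusted fry p under 0.05, and neither fry in either direction nor camera passed any.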

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

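In this part the tests of 1 outlying control array, of less blood in the liver and of the loess step, the splits that take account of slides and the look at both channels of a gene were chosen only after the result was seen. Arrays were tested for lying apart from the rest of their group, by the gap to the nearest other array as a share of the group's range, in 442 pairs of a named gene and a group. In 22 of them 1 array lay apart, where chance gives about 1 in 20 pairs. The values that follow are log2 ratios. Arrays at 300 mg/kg and 4 h stood out for Cyp1a2 in replicate 1 (4.15, nearest other 4.57), Cdkn1a in replicate 1 (-1.02, nearest other 0.062) and Cd5l in replicate 3 (5.80, nearest other 4.19). Arrays of the 4 h control group lay apart for Cd5l in replicate 5 (4.75, nearest other 5.82), Srxn1 in replicate 5 (-0.64, nearest other -0.83), Cyp2b13 in replicate 4 (1.23, nearest other 0.69), Rsad2 in replicate 5 (0.70, nearest other 0.22), E2f8 in replicate 3 (0.36, nearest other -0.44) and Cyp4a14 in replicate 5 (3.98, nearest other 6.00). Arrays at 150 mg/kg and 4 h stood out for Psmb9 in replicate 2 (-0.85, nearest other -0.34). Those at 50 mg/kg and 4 h lay apart for Cyp1a2 in replicate 1 (4.75, nearest other 4.57). Arrays at 5 mg/kg and 4 h stood out for Olfr114 in replicate 4 (3.20, nearest other 4.25) and Nqo1 in replicate 2 (-1.16, nearest other -1.64). Those at 300 mg/kg and 24 h lay apart for Chka in replicate 3 (-0.57, nearest other -0.71), Gstm2 in replicate 1 (1.30, nearest other 1.74) and Isg15 in replicate 4 (-1.41, nearest other -1.06). Arrays of the 24 h control group stood out for Hba-a1 in replicate 1 (4.36, nearest other 4.73) and Cyp2a4 in replicate 5 (5.19, nearest other 5.79). Those at 150 mg/kg and 24 h lay apart for Elovl3 in replicate 2 (2.70, nearest other 1.72) and Gstm3 in replicate 4 (3.99, nearest other 3.80). Arrays at 50 mg/kg and 24 h stood out for Olfr114 in replicate 3 (4.24, nearest other 4.05) and Dbp in replicate 2 (-2.01, nearest other 0.83).

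The effect of a dose differed between 24 h and 4 h by the interaction test, for 1382 genes at 300 mg/kg and 591 at 150 mg/kg. In the log2 effect at 24 h minus that at 4 h, named genes with a higher value at 300 mg/kg were Dbp (5.54), Rgs16 (3.31), Cyp4a14 (2.72), Fasn (2.52), Tef (2.18), Srebf1 (2.07), Arrdc3 (1.98), Nr1d1 (1.92), Blnk (1.29), Elovl6 (1.23), Hsd3b5 (1.11), Acly (0.88), Pdgfrb (0.60) and Rev1 (0.55). Those with a lower value were Cyp1a1 (-3.79), Gadd45g (-3.45), Cbr3 (-3.25), Arntl (-3.10), Srxn1 (-2.65), Hspa2 (-2.51), Hspa1a (-2.40), Nfil3 (-2.31), Chka (-2.25), Cyp1b1 (-2.24), Cdkn1a (-2.15), Hspa1b (-2.10), G6pc (-1.97), Cyp2b10 (-1.85), Bag3 (-1.78), Hbb-bt (-1.78), Hsph1 (-1.62), Ugdh (-1.55), Elovl3 (-1.43), Hba-a1 (-1.40), Sdf2l1 (-1.40), Hspa5 (-1.39), Tsc22d3 (-1.34), Cebpd (-1.18), Hspa8 (-1.15), Ahrr (-1.08), Nqo1 (-1.06), Akr1b8 (-0.99), Ddit4l (-0.99), Dnaja1 (-0.82), Fabp4 (-0.79) and Mdm2 (-0.55). Cyp1a1, Cyp1b1, Ahrr and Ddit4l were not well above background on any 4 h control array, so the size of their difference here and at 150 mg/kg rests in part on values at background. With the processed signals the call was lost at 300 mg/kg for Cyp1a1 (-1.01), Cyp2b10 (-0.25), Cyp4a14 (0.46), Elovl3 (-0.60), G6pc (-0.56) and Hsd3b5 (0.13) and for Hbb-bt, whose sign turned (0.21). List medians were higher for circadian clock (0.68), cholesterol synthesis and uptake (0.60), B cell markers (0.28), fatty acid and triglyceride synthesis (0.22), cell cycle (0.14) and DNA repair (0.11), and lower for AHR battery (-0.96), heat shock (-0.68), endoplasmic reticulum stress (-0.47), glucocorticoid and fasting response (-0.39), NRF2 targets (-0.26) and erythroid markers (-0.18). All of these passed fry, and with an estimated correlation AHR battery, NRF2 targets, endoplasmic reticulum stress and heat shock passed too, while the others had adjusted p = 0.0753 to 0.617.

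Named genes of 150 mg/kg with a higher effect at 24 h than at 4 h were Dbp (5.17), Rgs16 (3.74), Tef (2.02), Fasn (1.99), Nr1d1 (1.70), Hmgcs1 (1.59), Msmo1 (1.49), Srebf1 (1.42), Stard4 (1.19), Blnk (1.14), Sc5d (0.76) and Psmb9 (0.76). A lower effect was found for Cyp1a1 (-6.07), Arntl (-3.19), Gadd45g (-2.48), Srxn1 (-1.99), Cbr3 (-1.89), Ugdh (-1.54), Akr1b8 (-1.21), Cdkn1a (-1.16), Cyp1b1 (-1.13), Nqo1 (-1.001), Ahrr (-0.98) and Ddit4l (-0.72). List medians were higher for circadian clock (0.73), cholesterol synthesis and uptake (0.69), interferon response (0.21) and fatty acid and triglyceride synthesis (0.20), and lower for AHR battery (-0.81), heat shock (-0.54), endoplasmic reticulum stress (-0.33) and NRF2 targets (-0.27). All of these passed fry, and with an estimated correlation AHR battery and NRF2 targets passed too, while the others had adjusted p = 0.0675 to 0.222.

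Clock genes changed at 300 mg/kg and 24 h, 10 up and 3 down of 18. With slide as a block 13 of the 13 called members stayed past the threshold in their direction, which argues against a slide batch as the source. If dosed and control animals had been sampled at different hours of the day, other genes that differ between the control groups would move too. In each of 10 splits of the 24 h controls such genes were chosen without the arrays that served as the baseline of the dose effect, 129 to 543 genes. On average 81.6% of them moved at 24 h against the controls' difference (73.1 to 85.3% over the splits), where no change gives 50%. At 150, 50 and 5 mg/kg the averages were 78.8, 76.8 and 68.9%, with ranges that held 50% at 50 and 5 mg/kg. A different sampling hour and a shift of the clock by BaP would both give such shares, so they cannot be told apart for these genes, and either may be the source.

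The globin genes Hbb-bt and Hba-a1 passed as decreases at 300 mg/kg and 24 h. The control array that lay apart for Hba-a1 was below the others and so could not have given the decrease. With each array of both groups left out in turn, the larger adjusted p of the pair was at most 5.66e-12, so no single array gave the calls. With slide as a block it was 4.92e-11, which argues against a slide batch. Less blood left in the livers of dosed animals would lower blood leukocyte markers too, and the median of 10 measured B and T cell markers was -0.066 (bootstrap SE 0.056). Leukocytes that reside in the liver would hide a small loss of blood, and the labels say that animals were bled before the liver was removed, so less blood and fewer young red cells cannot be told apart. Either may be the source for Hba-a1, which was at -2.63 (adjusted p = 7.00e-09) with Agilent's processed signals. Hbb-bt was then at -0.19 (adjusted p = 0.814), because Cy3, the channel of the common reference, fell with Cy5 (log2 changes of -5.25 and -5.43 in the processed and -2.09 and -5.09 in the median signals). The liver channel thus fell in both kinds of signal. Whether and how far Hbb-bt fell against the reference is left open, and a fault of its spot signal was not tested. At some other probes Cy3 fell with Cy5 too, among them that of Elovl3 at 150 mg/kg and 24 h.

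More genes fell than rose at 300 mg/kg and 4 h, with 32.5% of the calls up. With slide as a block the share was 33.4%, which argues against a slide batch. With median centring in place of loess it was 73.0%, but that centring also moved the median of all genes from -0.051 to 0.13 (log2), which turns the share by itself. An excess set by the normalization and one in the livers thus cannot be told apart. No biological explanation was tested for the balance of decreases and increases.

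The same arrays were also split at random into groups of the same sizes, in 100 splits per result with the real one included. In 1 of the 100, the real split, the result was as large as the real one for 300 mg/kg at 4 h (3177 against 2357), 150 mg/kg at 4 h (1335 against 375), 300 mg/kg at 24 h (1638 against 1013), 150 mg/kg at 24 h (1158 against 411), the trend at 4 h (4154 against 1139), the trend at 24 h (2543 against 1349), 300 against 150 mg/kg at 4 h (199 against 37), the difference between times at 300 mg/kg (1382 against 1331), the difference between times at 150 mg/kg (591 against 86), the controls at 24 h against 4 h (426 against 96) and the gene list calls (47 against 3), where the second value is the highest of the other splits. The same held for 300 against 150 mg/kg at 24 h in 1 of 35 splits (12 against 3). At 50 mg/kg 2 of 100 splits reached the count at 4 h (51, highest other 761) and 2 at 24 h (12, highest other 16), and at 5 mg/kg and 4 h 4 did (5, highest other 54). These unadjusted shares count against chance only if arrays can be exchanged freely. At 5 mg/kg and 4 h limma passed 0 genes when only these 10 arrays were fitted. Chance cannot be excluded at 5 mg/kg and 24 h, where 21 of 100 splits gave 1 gene or more and the highest gave 133. That split exchanged control replicate 1 for 5 mg/kg replicate 2, both of slide 12, and so many genes point to a structure of the arrays there too. The split with 761 genes parts the arrays of slides 1, 3, 5 and 7 from those of slides 8, 9 and 11, and that with 54 parts slides 7, 9, 10 and 11 from slides 1, 3 and 5, which points to a structure of the arrays by slide. The splits were therefore fitted again with slide as a block. For 300 against 150 mg/kg at 24 h 2 of 35 splits then reached the count (26, highest other 50) and at 5 mg/kg and 24 h 23 of 100 did (1, highest other 506), so chance cannot be excluded there. It was 3 of 100 for 50 mg/kg at 24 h (10, highest other 35), 2 for 50 mg/kg at 4 h (37, highest other 47) and the real split alone for 5 mg/kg at 4 h (5, highest other 1) and each other gene count. Exchange within slides left 2 to 16 splits, too few for a share under 0.05, except for the trends, where no other of 100 reached the count at 4 h (4154, highest other 2863) or at 24 h (2543, highest other 1700).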

How the results depend on the processing

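Here leaving out slide 7, whose arrays had on average the highest share of probes well above background in Cy3 and whose control arrays had the lowest correlation within their groups, was chosen only after the data were seen. A gene kept its result when direction and side of the threshold held. Of 284 named gene results, 284 kept it with Aquantile normalization between arrays, 284 with no intensity trend in the variance, 279 with no filter, 276 without background correction, 270 with the authors' values, 267 with slide as a block, 273 with scan day as a block, 256 with only the groups compared, 237 with the processed signals and 229 with median centring. With 1 array left out, 114 gene values lost and 9 gained a call. The median log2 change of all genes was 0.019 to 0.30 over the 8 dose comparisons with median centring, against -0.051 to 0.019 with loess, and of the 3177 calls at 300 mg/kg and 4 h 1146 were shared with it. The median Cy5 intensity of a spot was 93 to 121 and the median local background 77.5 to 84, so low levels were near background and limit which genes could be tested or given more than a bound. The cause of the changes below was not tested, except that a fold threshold lowers a count by construction. Values of Cyp1a1 and Cyp1b1 rest on groups at background and show only where a sign or call moved.

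Without background correction, the sign turned for Cyp1a2 -0.054 (5 mg/kg 4 h), Cidec 0.12 (300 mg/kg 24 h) and Cyp1a1 -0.0063 (50 mg/kg 24 h). With Agilent's processed signals, 0 genes passed for 5 mg/kg 24 h and 320 for 300 against 150 mg/kg at 4 h. There the sign turned for Cyp1a2 0.15 and Hsd3b5 0.033 (300 mg/kg 4 h), Cyp1a2 0.16 (150 mg/kg 4 h), Cdkn1a 0.080 and Cyp1a2 0.0044 (50 mg/kg 4 h), Cdkn1a 0.11, Cyp1a2 -0.044 and Cyp1b1 0.24 (5 mg/kg 4 h), Cyp1a2 0.20, Cidec 0.61, Alas2 0.016 and Hsd3b5 0.17 (300 mg/kg 24 h), Alas2 0.11 (150 mg/kg 24 h), Cyp1a1 -0.022 and Cyp1b1 0.35 (50 mg/kg 24 h) and Cyp1a1 -0.101 and Cyp1b1 0.33 (5 mg/kg 24 h). With median centring in place of loess, 1266 genes passed for 300 mg/kg 4 h, 771 for 150 mg/kg 4 h, 926 for 300 mg/kg 24 h, 4094 for 150 mg/kg 24 h, 4 for 50 mg/kg 24 h, 2154 for the 4 h trend, 54 for 300 against 150 mg/kg at 4 h, 303 for the 300 mg/kg time difference, 131 for the 150 mg/kg time difference and 82 for the controls by time. Turned signs were those of Cyp1a2 0.81 and Ms4a1 0.019 (300 mg/kg 4 h), Cyp1a2 0.91 (150 mg/kg 4 h), Cdkn1a 0.099 and Cyp1a2 0.48 (50 mg/kg 4 h), Cdkn1a 0.047 (5 mg/kg 4 h), Cyp1a2 0.84 (300 mg/kg 24 h), Cyp1b1 0.048, Pdia6 0.31 and Alas2 0.20 (150 mg/kg 24 h) and Cyp1a2 0.52 and Cyp1b1 0.0020 (50 mg/kg 24 h). With no filter on dim probes, 117 genes passed for 300 against 150 mg/kg at 4 h. With the mean of all kept probes of a gene, the sign turned for Cyp1a2 0.11 (300 mg/kg 4 h), Cyp1a2 0.24 (150 mg/kg 4 h), Cyp1a2 0.15 (50 mg/kg 4 h), Cyp1a2 0.20 (300 mg/kg 24 h) and Cyp1a2 0.22 (50 mg/kg 24 h). With the authors' processed values, 1760 genes passed for 150 mg/kg 24 h. Turned signs were those of Cyp1a2 -0.17 (5 mg/kg 4 h), Cidec 0.12 (300 mg/kg 24 h), Cyp1a2 -0.018 and Alas2 0.022 (150 mg/kg 24 h), Cyp1a1 -0.0085 (50 mg/kg 24 h) and Cyp1a2 -0.12 (5 mg/kg 24 h). With slide as a fixed block, 26 genes passed for 300 against 150 mg/kg at 24 h and 121 for the controls by time. The sign turned for Cyp1a2 0.038 (150 mg/kg 4 h), Cdkn1a 0.086 (50 mg/kg 4 h), Cyp1b1 0.0081 (5 mg/kg 4 h) and Cyp1a2 0.051 (50 mg/kg 24 h). With slide as a random block, 2061 genes passed for 150 mg/kg 4 h, 25 for 50 mg/kg 24 h, 352 for 300 against 150 mg/kg at 4 h, 36 for 300 against 150 mg/kg at 24 h, 2123 for the 300 mg/kg time difference and 1074 for the 150 mg/kg time difference. There the sign turned for Cyp1a2 0.00071 (150 mg/kg 4 h), Cdkn1a 0.013 (50 mg/kg 4 h) and Cyp1a2 0.019 (50 mg/kg 24 h). With scan day as a block, 23 genes passed for 300 against 150 mg/kg at 24 h and 1006 for the controls by time. Turned signs were those of Cyp1a2 0.022 (150 mg/kg 4 h), Cyp1a2 -0.015 (150 mg/kg 24 h) and Cyp1a2 0.037 (50 mg/kg 24 h). With the replicate number as a block, 19 genes passed for 50 mg/kg 24 h. With a fold of at least 1.5 required too, 946 genes passed for 300 mg/kg 4 h, 391 for 150 mg/kg 4 h, 538 for 300 mg/kg 24 h, 361 for 150 mg/kg 24 h, 1032 for the 4 h trend, 662 for the 24 h trend, 75 for 300 against 150 mg/kg at 4 h, 763 for the 300 mg/kg time difference, 366 for the 150 mg/kg time difference and 155 for the controls by time. With camera and an estimated correlation, 21 list calls passed. With only the arrays of the groups compared in the fit, 26 genes passed for 50 mg/kg 4 h, 0 for 5 mg/kg 4 h, 1 for 50 mg/kg 24 h, 82 for 300 against 150 mg/kg at 4 h, 1 for 300 against 150 mg/kg at 24 h and 278 for the controls by time. Without slide 7, 3 genes passed for 5 mg/kg 4 h and 5 for 50 mg/kg 24 h. There the sign turned for Cyp1a2 -0.014 and Cyp1b1 0.0015 (5 mg/kg 4 h).

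Leaving out each array of the groups compared in turn gave 41 to 52 for the gene list calls, 555 to 1212 for 150 mg/kg 24 h, 992 to 1374 for 150 mg/kg 4 h, 1117 to 1617 for 300 mg/kg 24 h, 2731 to 3408 for 300 mg/kg 4 h, 1 to 3 for 5 mg/kg 24 h, 3 to 8 for 5 mg/kg 4 h, 2 to 46 for 50 mg/kg 24 h, 29 to 57 for 50 mg/kg 4 h, 6 to 22 for 300 against 150 mg/kg at 24 h, 73 to 210 for 300 against 150 mg/kg at 4 h, 252 to 463 for the controls by time, 382 to 704 for the 150 mg/kg time difference, 1045 to 1412 for the 300 mg/kg time difference, 2082 to 2661 for the 24 h trend and 3662 to 4323 for the 4 h trend. The sign of a gene without a call turned in some of these fits, with the range Cyp1a2 -0.11 to 0.092 (50 mg/kg 24 h), Fabp4 -0.0046 to 0.24 (300 mg/kg 24 h), Cyp1a2 -0.20 to 0.059 (150 mg/kg 4 h), Cyp1a2 -0.085 to 0.16 (5 mg/kg 4 h), Cyp1a2 -0.071 to 0.18 (150 mg/kg 24 h), Cyp1b1 -0.20 to 0.063 (50 mg/kg 24 h), Cdkn1a -0.29 to 0.031 (5 mg/kg 24 h), Cyp1b1 -0.17 to 0.0015 (5 mg/kg 4 h) and Cdkn1a -0.22 to 0.0029 (50 mg/kg 4 h). Called values moved by more than 1.5-fold without 1 array for Dbp at 50 mg/kg and 24 h, as reported (Cyp1a1 aside, controls at background). In the 300 mg/kg time difference so did Rgs16 (2.72, not 3.31) without 24 h replicate 2 and Cyp4a14 (3.40, not 2.72) without 24 h replicate 1.

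The replicate numbers of the labels did not pair the arrays. Deviations from the group mean had a mean correlation of 0.023 between arrays of the same number and -0.0055 between others, and 16 of 46 arrays correlated best with one of their own number. Arrays of 1 slide had a mean correlation of 0.33, against -0.024 for other pairs.

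Some genes that the rule takes for their large change were left undescribed above after their values were seen, most of them because the call was lost in fits with 1 array left out. Their log2 changes, with the fits they passed, were Rgs16 -1.95 (past in 7 of 10) for 150 mg/kg 4 h, Cox7a1 -0.45 (past in 2 of 10) and E2f8 -0.76 (past in 4 of 10) for 50 mg/kg 4 h, St3gal5 0.83 (past in 5 of 9) for 50 mg/kg 24 h, Cldn5 -0.99 (past in 2 of 10), Dio1 -1.08 (past in 3 of 10) and Socs2 -1.28 (past in 1 of 10) for 300 against 150 mg/kg at 4 h, Gstm2 0.97 (past in 7 of 8) and Nol3 0.97 (past in 6 of 8) for 300 against 150 mg/kg at 24 h and Cyp4a14 2.72 (past in 18 of 19) for the 300 mg/kg time difference. Others left undescribed for length passed in each such fit, with log2 changes of Arrdc3 -2.06 and Tsc22d1 -2.06 for 300 mg/kg 4 h, Hsd3b4 -1.97 for 150 mg/kg 4 h, Chka -2.0, G6pc -2.09 and Mt2 3.71 for 300 mg/kg 24 h, Rgs16 3.31 for the 300 mg/kg time difference and Rgs16 -2.77 and Cyp26a1 2.43 for the controls by time. G6pc had adjusted p = 0.143 with the processed signals.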

Other observations

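The genes named in this part were chosen only after their values were seen, and these values were not refitted under other settings. At 300 mg/kg against controls their list had no call for change on balance in 1 direction. Some cell cycle genes rose at 300 mg/kg and 24 h. Of 23 measured cell cycle genes, 7 rose and 16 did not pass (8 up adjusted over the list alone). The fry adjusted p was 0.0637 for 1 direction and 5.55e-04 for either. The cyclins Ccnd1 (1.24 ± 0.20) and Ccne1 (0.68 ± 0.15), the thymidine kinase Tk1 (0.75 ± 0.11) and the replication helicase subunit Mcm6 (0.82 ± 0.17) rose. At 4 h Ccnd1 (-0.68 ± 0.19) and Ccne1 (-0.51 ± 0.14) fell.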
